A study of Mus musculus with 12 samples.

How the data were processed

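RNA from 12 bulk ovarian tumour samples was assayed, per the labels, with an Ion AmpliSeq custom panel, a targeted method in which cDNA of a chosen set of genes is amplified by multiplex PCR and the amplicons are sequenced. The labels put 6 tumours in a vehicle group and 6 in an olaparib group, and state that the panel targeted 4604 mouse genes. The genome build was mm10, per the submitters' processing notes. The aligner, the counting method and any filter were not given in the sources used here, and neither were the positions of the amplicons within each gene.

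The series has 1 deposited table, with 1 line per gene name and 12 columns of values. The headings of those columns matched the title, description or other label of 0 of the 12 samples. Columns were not assigned to tumours by their order or by their values, and whether the values would separate the groups was not examined. The 12 columns of values were therefore not used here. No depth per tumour, expression level, fold change or test of olaparib against vehicle was computed, and the comparison planned before the data were examined (a test per gene, tests of gene lists, alternative normalizations, filters and left-out samples) was not run.

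The gene names of the deposited table were used, since they need no assignment to a tumour. They were read with Python 3.11.15 and matched to gene symbols of GENCODE release M21, whose build, GRCm38, is the one also called mm10. A name without a match was looked up among the symbols and synonyms of the RefSeq gene table for assembly GRCm38.p6 and was placed when it led to a single gene. This placed 4585 names by symbol and 14 by another name, and left 5 unplaced. Coordinates are those of whole genes in GENCODE M21, 1-based, and not those of amplicons.

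The gene names of the table were counted against 31 lists of mouse genes that were written before the data were examined. Of these, 3 were set as primary and 27 as secondary lists of pathways and cell types, and 1 held housekeeping genes. Members that are older and newer names of 1 gene were counted once. The count of list members on the panel was also made with the symbols as written in the lists, without synonyms, an alternative chosen after seeing the data. The genes named below are those of a set fixed before the data were examined, and members of the lists given as examples after seeing which were on the panel.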

Results

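The study collected ovarian tumours from mice given olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2, at 50 mg/kg per day (6 tumours) or vehicle (6 tumours). The tumours lacked Brca1, a gene of homologous recombination, and Trp53, the gene of the tumour suppressor p53, carried c-Myc, and had been transplanted into the ovaries of FVB/NJ mice. RNA of the whole tumour was assayed, so each library could hold transcripts of tumour cells together with those of immune and stromal cells. The cell content of the libraries was not examined. The series title names the question as whether PARP inhibition elicits immune responses against Brca1-deficient tumours through STING, the adaptor protein of cytosolic DNA sensing. The value columns of the deposited table carry headings that match no tumour's label, and they were not used. Expression in olaparib-treated and vehicle-treated tumours was therefore not compared, and the results below describe which genes the panel was built to measure.

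The table listed 4604 distinct gene names, as many as the labels give for the panel. Of these names, 4599 were placed on the mm10 assembly, and 4577 of the placed genes were protein-coding. The panel thus held 20.9% of the 21924 protein-coding genes annotated in GENCODE M21. The other 22 placed genes included 5 long intergenic non-coding RNAs and 11 polymorphic pseudogenes. Chromosome 11 carried 405 of the 4599 placed genes, the most of any chromosome, and has 1637 annotated protein-coding genes. Chromosome 7, which has more annotated protein-coding genes (2021), carried 340 of the placed genes. Chromosome 1, which has fewer (1203), carried 306. The counts of placed genes per chromosome include the genes that are not protein-coding.

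The genes named for the tumour model (Brca1, Trp53 and Myc) were on the panel, as were Parp1 and Parp2, the genes of the drug targets named above. Parp3, another gene of the PARP family, was not listed. Brca1 (ENSMUSG00000017146.12) spans bases 101488764 to 101551955 of the minus strand of chromosome 11. Trp53 (ENSMUSG00000059552.13) lies on the same chromosome at 69580359 to 69591873, on the plus strand. Myc (ENSMUSG00000022346.15), a transcription factor that drives cell growth, lies on chromosome 15 at 61985391 to 61990374. Parp1 lies on chromosome 1 at 180568924 to 180601254, and Parp2 on chromosome 14 at 50807841 to 50821301. The amplicon positions were not given in the sources used here, so whether the Brca1 and Trp53 amplicons fell inside the deleted part of each gene was not examined. Whether the Myc amplicons would read the c-Myc that the tumours carried was not examined either.

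The 3 primary lists concerned immune responses. All 17 cytotoxic effector genes were on the panel, among them Gzmb and Prf1, which encode the granule proteins granzyme B and perforin, Ifng, which encodes interferon gamma, and the T cell chemokine Ccl5. Of 24 T cell markers, 23 were listed, including the T cell receptor component Cd3e and the coreceptors Cd4 and Cd8a, and only Cd27 was not. Of 38 type I interferon-stimulated genes, 27 were listed. The 11 that were not listed included Isg15 and Ifit3, which are widely used to read an interferon response.

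Of 18 STING pathway genes, 11 were on the panel. Tmem173, which encodes STING, lies on chromosome 18 at 35733679 to 35740554 and was listed, as was Ifnb1, which encodes interferon beta, on chromosome 4 at 88522025 to 88522774. The gene of the DNA sensor cGAS was not listed under Mb21d1 or under its newer name, and neither was Trex1, which encodes a DNA exonuclease that degrades cytosolic DNA. Of 24 interferon-gamma-inducible genes, 19 were listed, including the T cell-attracting chemokines Cxcl9 and Cxcl10, which lie near each other on chromosome 5.

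Other immune groups were covered as follows. All 13 genes of MHC class II presentation and all 11 regulatory T cell markers were listed. The panel held 17 of 18 immune checkpoint genes, among them Pdcd1 and Cd274, which encode PD-1 and its ligand PD-L1, and 32 of 34 chemokines. It held 22 of 24 macrophage and monocyte markers, 16 of 20 dendritic cell markers, 16 of 20 neutrophil markers and 13 of 15 natural killer cell markers. It held 13 of 17 genes of MHC class I presentation and 22 of 26 NF-kappaB targets and inflammatory cytokines. Of 24 B cell and plasma cell markers, 18 were listed. The 6 not listed were the immunoglobulin genes Ighm, Ighd and Igkc, the B cell genes Ms4a1 and Cd79a, and Sdc1.

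For DNA repair and the cell cycle, the panel held 19 of 29 homologous recombination and Fanconi genes. It held 7 of 18 genes of the PARP family and base excision repair, in which Parp3, Parg and Xrcc1 were among the 11 not listed. It held 14 of 28 S phase and replication genes, without Pcna, 20 of 27 proliferation and mitosis genes, 14 of 22 p53 targets and 22 of 25 apoptosis genes. Of the cell types of the tumour other than immune cells, 15 of 23 epithelial tumour cell markers, 17 of 22 fibroblast and matrix markers and 14 of 18 endothelial markers were listed. The panel held 16 of 22 hypoxia and glycolysis genes. For tissues that a dissected ovarian tumour may carry along, it held 8 of 15 granulosa and steroidogenic markers, 8 of 12 adipocyte markers, 6 of 12 skeletal muscle markers and 2 of 11 erythroid markers. Of 18 housekeeping genes, 9 were listed.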

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

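The labels do not state that equal replicate numbers in the vehicle and olaparib groups mark a pair. Apart from that, no paired analysis was possible because the columns of values match no sample label. For the same reason none of the alternatives planned for the comparison of olaparib with vehicle (other normalizations, filters, tests, covariates, thresholds and left-out samples) was run. The other alternatives were chosen after seeing the data. Matching panel names to the annotation by symbol alone placed 4585 genes in place of 4599. Separately, when the symbols of the lists were matched to the panel names as written, without synonyms, the counts of listed genes were unchanged in 30 of the 31 lists, and hypoxia and glycolysis genes went from 16 to 15.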

Other observations

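One of the 5 names that could not be placed was a calendar date written in the gene column, 11 September 2018. The others were D830031N03Rik, F630111L10Rik, Ikbkap and Tmem5, each a gene name that led to no single GENCODE M21 gene by symbol or by RefSeq synonym.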
